A study of Homo sapiens with 12 samples.

How the data were processed

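Total RNA was isolated with miRNeasy kits, per the labels, from 12 samples of RPTEC/TERT1 cells, an hTERT-immortalised human renal proximal tubule epithelial cell line, and was measured with the NanoString nCounter human miRNA panel, which counts fluorescent barcodes hybridised to each miRNA without amplification. The labels give 4 groups of 3 libraries, formed by a soft or stiff polyacrylamide gel and by no treatment or medium conditioned by bone marrow mesenchymal stem cells (CM). They do not say whether the 3 libraries of a group came from separate cultures, and a control medium without stem cells is not given in the sources used here. Culture lasted 5 days, and CM replaced the medium on day 4 for 24 h.

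The authors deposited raw barcode counts for each probe and library, in counts, and a second table of normalised signal. Set against the raw counts, the deposited signal equalled the count times 1 factor per library, from 0.766 to 1.47, for all but the positive and negative control probes, which were left unscaled. The largest relative deviation over 814 probes was 0.275%, and 17 values had been raised to 1. The factor brought the geometric mean of the 100 probes with the highest mean count to 412 in every library. The counting software and its version are not given in the sources used here.

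All comparisons started from the raw counts. Of 828 probes, 798 were endogenous miRNA probes, 6 positive controls, 8 negative controls, 6 ligation controls, 5 housekeeping mRNAs and 5 plant or worm miRNAs. An endogenous probe was tested when its count exceeded the mean plus 2 SD of the negative controls of the same library in at least 3 of the 12 libraries. This kept 207 probes and left 591 untested. Counts were scaled with the trimmed mean of M values (TMM) of edgeR 4.0.16 in R 4.3.3, with factors from 0.530 to 1.55, and levels are given as CPM, counts relative to the scaled library size as edgeR defines them. The quasi-likelihood F test of edgeR, with robust empirical Bayes, was fitted to all 12 libraries with 1 mean per group. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over the 207 probes, and all tests were two-sided. Errors of log2 fold changes are standard errors from that model, errors of CPM are SD, and n is 3 libraries per group or 6 where the groups of both gels or both media were combined.

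The 7 comparisons were stiff against soft gel without treatment, CM against untreated on the stiff gel, the same on the soft gel, stiff against soft gel under CM, the interaction of gel and CM, and the means of the CM effect over both gels and of the gel effect over both media. The comparisons, tests, probe filter, miRNA lists and the alternatives other than 3 named below were chosen before the data were examined. The 21 lists were the let-7 family, the miR-200 family with miR-205, the miR-30, miR-29, miR-15/16 and miR-99/100/125 families, the miR-17-92 and miR-23/27/24 clusters, kidney tubule-enriched, fibrosis-promoting, fibrosis-opposing, matrix stiffness-linked, inflammation-linked, p53-linked and hypoxia-linked miRNAs, mesenchymal stromal markers, the DLK1-DIO3 cluster, stromal vesicle cargo, blood and endothelial markers, markers of absent tissues, and the placental C19MC cluster. Lists with at least 3 tested members, 19 in all, were tested with fry of limma 3.58.1, adjusted over the 133 pairs of list and comparison. Its directional p asks whether the members move, on balance, one way, and its mixed p whether they change in either direction. Neither compares a list with other miRNAs. Camera with an estimated correlation between members was the alternative.

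The alternatives were DESeq2 1.42.0 with its size factors, scaling on the top 100 probes, on total counts, on the housekeeping mRNAs or on the positive controls, subtraction of the negative control mean, no filter, a mean count of at least 100, limma on the log2 of the authors' values plus 1, limma-trend, a prior that was not robust, fits of the 2 compared groups alone, the replicate number as a block, and leaving out each library in turn. After the data were seen, 3 more were added. These were the level of the probe shared by miR-4454 and miR-7975 as a covariate, leaving out the 4 libraries in which that probe took over 50% of the endogenous counts, and a restriction to the 124 probes with a mean count above 54, the highest count of any plant or worm probe.

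The procedure was tested on simulated data with the means and dispersions of these libraries, in 20 runs with 200 of 798 probes changed. The fits called 17.6%, 69.4% and 97.2% of tested probes changed 1.5, 2 and 3-fold for CM on the stiff gel, 54.4%, 96.5% and 99.4% for the mean over both gels, and 7.65%, 26.6% and 70.5% for the interaction. False calls made up 4.55%, 3.72% and 6.39% of the calls in these 3 comparisons. The counts were drawn independently for each probe and library, without the correlations seen between real libraries. Other assignments of the real libraries to groups gave up to 6, 26 and 10 calls in these 3 comparisons. Those assignments left some libraries in their real groups, so a real effect may have added to these calls. Without the correlations, the simulated shares may not hold for the real data. A shift of the miR-30 family over both gels passed fry in 20 of 20 runs at 1.5-fold and in 1 of 20 runs without a shift. There p was adjusted over the lists of that comparison alone. The real tests were adjusted over 133 pairs, so the share that passes may differ for them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

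No library was left out of the main comparisons. Total endogenous counts ranged from 137956 to 434191 per library. A share of counts in a single library is given with its 95% Wilson interval, which covers counting error only. The replicate numbers were checked as pairs and did not pair the libraries: residuals of libraries with the same number had a median correlation across probes of -0.10, against 0.04 for different numbers, and 3 of 12 libraries resembled a library of their own number most.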

Results

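The series measured miRNAs in RPTEC/TERT1 renal proximal tubule cells on soft or stiff polyacrylamide gels, each without treatment or with medium conditioned by bone marrow mesenchymal stem cells (CM), in 4 groups of 3 libraries. By the labels it asked how the stiffness of the gel and the CM bear on the miRNAs of these cells. Total endogenous counts were 231269, 176711 and 175155 in the untreated soft-gel libraries, 421456, 414239 and 155554 in the untreated stiff-gel libraries, 192288, 137956 and 203042 in the CM soft-gel libraries, and 170126, 434191 and 205014 in the CM stiff-gel libraries. A single probe, shared by hsa-miR-4454 and hsa-miR-7975, took between 11.1% (95% interval 10.95 to 11.24) and 72.8% (72.6 to 72.9) of these counts. It exceeded 50% in 4 libraries: untreated soft-gel replicate 1 (66.9%, 66.7 to 67.1), untreated stiff-gel replicates 1 (72.7%, 72.5 to 72.8) and 2 (72.8%, 72.6 to 72.9), and CM stiff-gel replicate 2 (70.1%, 70.0 to 70.3). Whether its signal is RNA of the cells or arises in the assay is not given in the sources used here. Without that probe the totals ranged from 76492 to 157101 counts. Between 118 and 211 endogenous probes per library lay above the library's negative control threshold of 21.7 to 60.8 counts.

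**Figure D1:**
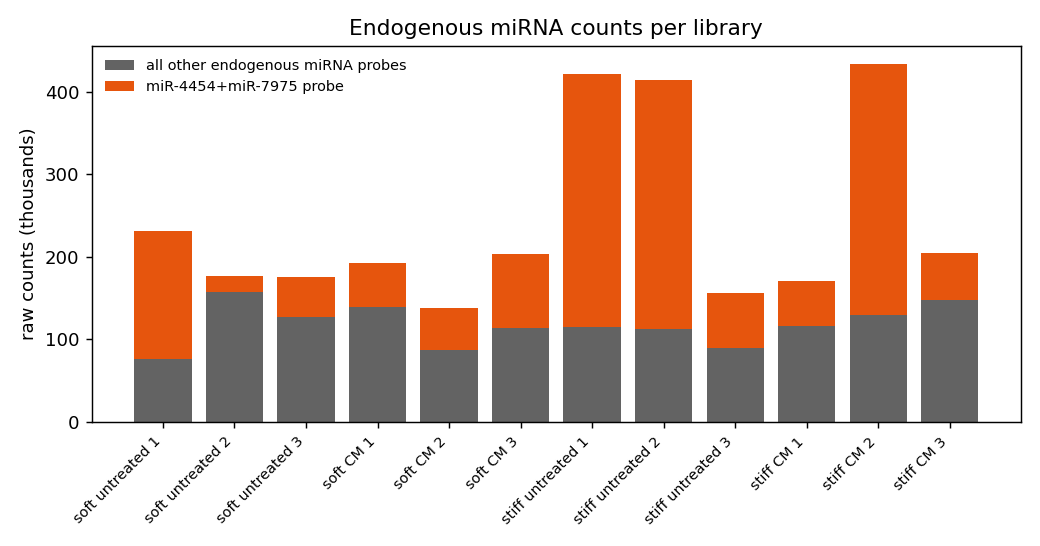
Endogenous barcode counts of each of the 12 libraries, divided into the probe shared by miR-4454 and miR-7975 and all other miRNA probes, on a linear axis from 0. The other probes together hold 76492 to 157101 counts, while the shared probe ranges from 19610 to 306289 counts.

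After that probe, the miRNA probes with the highest levels were those of let-7a-5p, at a mean of 82169 CPM over the 12 libraries, and let-7b-5p, at 46111 CPM, both of the differentiation-linked let-7 family. The collagen-targeting miR-29b-3p followed at 35322 CPM, then miR-23a-3p at 26625 CPM, let-7g-5p at 21666 CPM and miR-21-5p, a miRNA much studied in fibrosis, at 15908 CPM. Of related sequence, miR-125b-5p and miR-125a-5p reached 12615 and 11956 CPM, and miR-10a-5p, from the HOXB gene cluster, 12224 CPM. Counts of different probes also depend on how well each is ligated and hybridised, so this order is one of probe signal. None of these 9 was called in any of the 7 comparisons with edgeR.

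Over both gels, CM changed 11 of the 207 tested miRNAs, 7 higher and 4 lower, with edgeR. The epithelial miR-205-5p, which represses the transcription factors ZEB1 and ZEB2, had the largest fitted rise of the 7, 1.02 ± 0.20 on the log2 scale (SE, adjusted p = 0.00509). It went from 4845 ± 1382 to 9875 ± 2083 CPM (SD, n = 6), higher in 6 of 6 CM libraries than the untreated mean of their own gel. With the background subtracted miR-3605-3p (2.78) and miR-216a-5p (1.15) rose more than miR-205-5p (1.04). The probe of miR-365a-3p and miR-365b-3p, which share 1 mature sequence, rose by 0.67 ± 0.12 (adjusted p = 0.00509, 6 of 6 libraries), from 765 ± 48.4 to 1223 ± 169 CPM. For miR-24-3p, of the miR-23/27/24 clusters, the rise was 0.60 ± 0.12 (adjusted p = 0.00509, 6 of 6), from 1784 ± 133 to 2692 ± 371 CPM. Of 4 tested miRNAs encoded next to each other on the X chromosome 3 fell: miR-424-5p by 0.94 ± 0.20 (adjusted p = 0.00707), miR-503-5p by 0.91 ± 0.18 (0.00509) and miR-450a-5p by 0.71 ± 0.14 (0.00509), each lower in 6 of 6 CM libraries. Their levels went from 460 ± 116 to 240 ± 58.9, from 732 ± 86.8 to 389 ± 102 and from 277 ± 32.0 to 168 ± 19.4 CPM. The remaining neighbour, miR-542-5p, stood at 0.37 ± 0.24 without passing (adjusted p = 0.443), above the untreated mean in 4 of 6 CM libraries. In each stiff-gel group 1 of 3 libraries exceeded the negative control threshold for it. Its change was 0.86 with the background subtracted, so the size is not fixed.

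The other calls over both gels were miR-216a-5p (0.78 ± 0.16, adjusted p = 0.00600, 6 of 6 libraries higher), miR-302f (0.57 ± 0.14, 0.0256, 6 of 6), miR-3605-3p (0.86 ± 0.23, 0.0391, 5 of 6), miR-483-3p (0.60 ± 0.17, 0.0485, 3 of 6) and, lower, miR-30e-3p (-0.52 ± 0.13, 0.0250, 6 of 6). The CM and untreated libraries of both gels did not overlap at all for miR-365a-3p/miR-365b-3p, miR-24-3p, miR-503-5p, miR-450a-5p and miR-424-5p. Mean counts were low for miR-3605-3p (33.5), miR-302f (45) and miR-450a-5p (48.1). For miR-3605-3p 0 of 3 untreated stiff-gel libraries exceeded the negative control threshold. The size of its change is thus not fixed, and was 2.78 with the background subtracted. The changes of miR-216a-5p, miR-302f and miR-450a-5p were then 1.15, 0.93 and -1.08, so these sizes depend on the background as well. With DESeq2 8 miRNAs were called, 4 higher and 4 lower. Scaling on total counts, which moved the median of all tested probes to 0.47, left 1 call, higher, and scaling on housekeeping mRNAs left 1, higher, while scaling on the positive controls, with a median of 0.19, gave 19 higher and 0 lower. All 11 kept their direction in each setting that tested them.

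The probe shared by miR-4454 and miR-7975 exceeded 50% of counts in 3 of the 6 untreated and 1 of the 6 CM libraries. With its level as a covariate 31 miRNAs were called over both gels, among them all 11, and without those 4 libraries 13 were called, of which 4 were among the 11. There all 11 kept their sign, 6 with a larger and 5 with a smaller fold change, and 10 had an unadjusted p under 0.05. Leaving out untreated soft-gel replicate 1 gave 38 calls, 26 higher and 12 lower, and leaving out untreated soft-gel replicate 3 gave 7. The calls of miR-205-5p, miR-216a-5p, miR-365a-3p/miR-365b-3p, miR-24-3p, miR-424-5p, miR-503-5p and miR-450a-5p stood in all 12 fits that left out 1 library. The call of miR-30e-3p ended without untreated soft-gel replicates 2 or 3, untreated stiff-gel replicate 2, CM soft-gel replicate 1 or CM stiff-gel replicate 1. That of miR-302f ended without untreated soft-gel replicate 3, untreated stiff-gel replicates 1 or 3, CM soft-gel replicates 1 or 3, or CM stiff-gel replicates 1 or 3. The calls of miR-3605-3p and miR-483-3p each stood in 4 of the 12 fits: for miR-3605-3p those without untreated soft-gel replicate 1, CM soft-gel replicate 1 and CM stiff-gel replicates 1 and 2, and for miR-483-3p those without untreated soft-gel replicates 1 and 2, untreated stiff-gel replicate 2 and CM soft-gel replicate 2. In the 12 fits the log2 changes ranged from -0.64 to -0.44 for miR-30e-3p, from 0.50 to 0.64 for miR-302f, from 0.69 to 0.99 for miR-3605-3p and from 0.49 to 0.72 for miR-483-3p, each with an unadjusted p under 0.05.

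**Figure D2:**
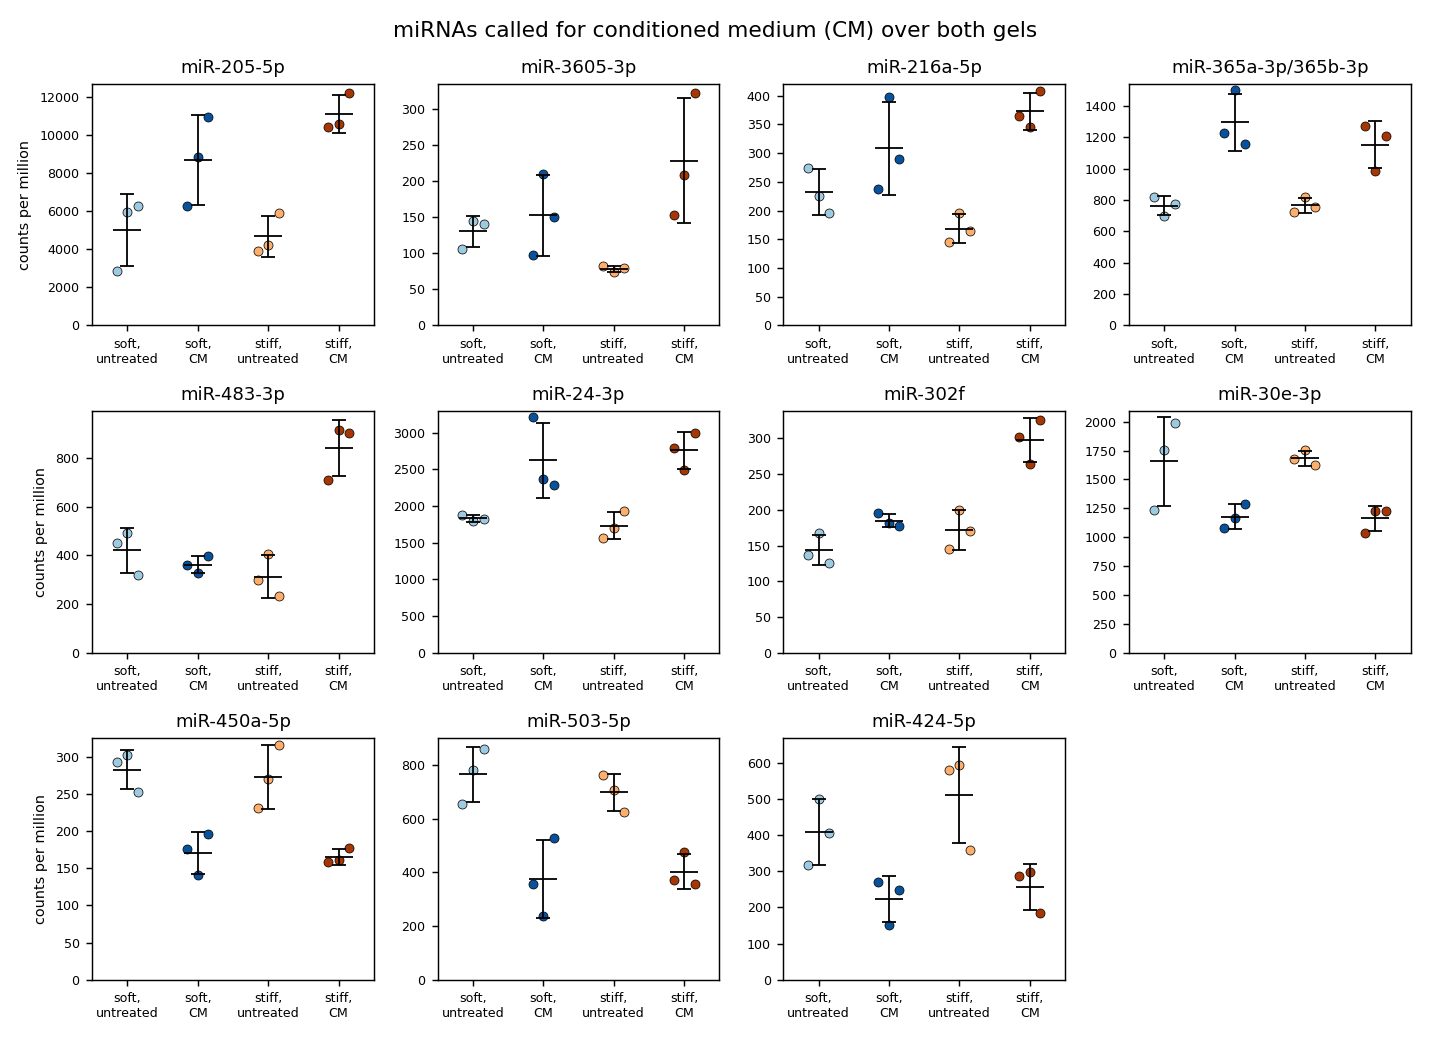
CPM in each library, by group, for the 11 miRNAs called with CM over both gels, on linear axes from 0, with group means as horizontal lines and SD as error bars (n = 3). For miR-24-3p, miR-365a-3p/miR-365b-3p, miR-424-5p, miR-503-5p and miR-450a-5p the 6 CM libraries do not overlap the 6 untreated ones.

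The miR-15/16 family, whose members restrain the cell cycle, held 5 tested members, of which 2 fell over both gels, miR-424-5p and miR-503-5p, and 0 rose. Adjusted over the list alone, miR-16-5p passed as well, in the other direction (0.48 ± 0.15, adjusted p = 0.0725 over all miRNAs), and miR-15a-5p had a log2 change of -0.36 ± 0.17 that did not pass. The family's directional fry p was 0.0398 (adjusted p = 0.311), and p = 0.106 with an estimated correlation. Of 5 tested members of the miR-200 family with miR-205, 1 rose, miR-205-5p, and miR-141-3p had a change of 0.49 ± 0.23 that did not pass, with a fry adjusted p of 0.232 for the list. Of the 7 tested members of the miR-30 family, abundant in kidney epithelium, 1 fell, miR-30e-3p, and 0 rose, while miR-30c-5p had a change of 0.27 ± 0.14 that did not pass (fry adjusted p = 0.733). The miR-23/27/24 clusters had 1 of 5 tested members higher, miR-24-3p, and miR-27a-3p at 0.28 ± 0.15 without passing (fry adjusted p = 0.412). Counts adjusted over the list alone were the same 1 for each of these last 3 lists.

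Among lists named for function, the fibrosis-promoting list had 1 of 5 tested members higher over both gels, also adjusted over the list alone. This was miR-216a-5p, while miR-155-5p stood at 0.17 ± 0.12 without passing (fry adjusted p = 0.241). Of the 10 tested fibrosis-opposing miRNAs 0 passed with edgeR, also adjusted over the list alone, with miR-29a-3p at 0.32 ± 0.16 (fry adjusted p = 0.940). The list of stromal vesicle cargo, chosen from general knowledge, had 1 of 10 tested members called, miR-24-3p, also adjusted over the list alone. Its mixed fry test passed (adjusted p = 0.0182) and its directional test did not (adjusted p = 0.641, and p = 0.584 with an estimated correlation), with miR-22-3p at 0.25 ± 0.12 and miR-125b-5p at 0.26 ± 0.13, neither passing. The 3 tested kidney tubule-enriched miRNAs, miR-10a-5p (-0.32 ± 0.13), miR-10b-5p (-0.33 ± 0.13) and miR-194-5p (-0.21 ± 0.15), did not pass over all miRNAs, and turned to 0.02, 0.04 and 0.10 when scaled on total counts. Adjusted over the list alone 2 of them passed, miR-10a-5p and miR-10b-5p (fry adjusted p = 0.238 for the list).

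The 4 tested mesenchymal stromal markers, listed as a check for RNA carried over from the cells that made the CM, all had negative changes over both gels and 0 passed with edgeR, also adjusted over the list alone. They were miR-218-5p (-0.49 ± 0.27), miR-10b-5p, which the kidney list also holds, miR-140-5p (-0.17 ± 0.13) and miR-199b-5p (-0.09 ± 0.19), and the last 2 turned to 0.21 and 0.27 when scaled on total counts. The fry p of the list was 0.00105 (adjusted p = 0.104), and p = 0.0635 with an estimated correlation. Of 10 matched stromal probes 4 were tested. The untested ones all had higher mean raw counts with CM, such as miR-143-3p (23.5 against 16.7) and miR-199a-5p (21.3 against 18.8). These counts were not scaled for library size. Such rises were not limited to stromal probes. Among untested markers of absent tissues, miR-302b-3p (19 against 13.3) and miR-499a-5p (11.3 against 7.17) were also higher, while miR-367-3p (19.8 against 21.7) and miR-208b-3p (14.2 against 14.3) were lower. Each untested stromal probe was above the negative control threshold in at most 1 library, so the check cannot decide on carried-over RNA. In the imprinted DLK1-DIO3 cluster, active in mesenchymal cells, 0 of 5 tested members passed over all miRNAs and 1 passed adjusted over the list alone, miR-495-3p (0.62 ± 0.19, adjusted p = 0.0730 over all miRNAs, fry adjusted p = 0.814 for the list).

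In the other 9 tested lists 0 members passed over both gels, over all miRNAs or adjusted over the list alone, with edgeR. The fry adjusted p was 0.940 for the let-7 family, with let-7f-5p at 0.41 ± 0.20, 0.940 for the miR-29 family, 0.983 for the matrix stiffness-linked list, with miR-301a-3p at -0.16 ± 0.14 (0.24 when scaled on total counts), and 0.965 for the miR-17-92 clusters, with miR-92a-3p at 0.34 ± 0.18. It was 0.897 for the miR-99, miR-100 and miR-125 family, with miR-99a-5p at -0.44 ± 0.15, 0.646 for the inflammation-linked list, with miR-212-3p at 0.45 ± 0.19, 0.983 for the p53-linked list, with miR-107 at 0.18 ± 0.15, 0.595 for the hypoxia-linked list, with miR-193b-3p at 0.57 ± 0.24, and 0.733 for the markers of absent tissues, with miR-137 at 0.17 ± 0.16. Over all 7 comparisons 0 of the 133 directional list tests passed with fry and 0 with camera. The directions of fry and camera differed in 14 of them, where the fry p ranged from 0.668 to 0.986. List medians and means over both gels differed in sign for the fibrosis-opposing list (-0.01 and 0.05), and for the matrix stiffness-linked list the median of 0.02 and the downward direction of fry differed. Over both gels, miR-10a-5p, miR-15a-5p, miR-99a-5p, miR-193b-3p and miR-495-3p passed over all miRNAs without untreated soft-gel replicate 1. So did miR-10b-5p without that library or CM soft-gel replicate 2, and miR-16-5p without that library or untreated stiff-gel replicate 3. For miR-141-3p, miR-193b-3p, miR-199b-5p, miR-218-5p and miR-495-3p 0 of 3 untreated stiff-gel libraries exceeded the negative control threshold. The sizes of their changes are thus not fixed.

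On the stiff gel, CM changed 12 miRNAs, 10 higher and 2 lower, and the 3 CM libraries did not overlap the 3 untreated ones for any of the 12. A rise of 1.42 ± 0.24 on the log2 scale (adjusted p = 0.00461) took miR-483-3p, encoded within the IGF2 gene, from 312 ± 87.3 to 841 ± 116 CPM. More abundant miRNAs that rose were miR-205-5p, by 1.25 ± 0.28 (adjusted p = 0.0198) from 4670 ± 1073 to 11074 ± 986 CPM, miR-16-5p, by 0.75 ± 0.21 (0.0434) from 5494 ± 1226 to 9262 ± 1427 CPM, and miR-24-3p, by 0.67 ± 0.16 (0.0267) from 1733 ± 186 to 2760 ± 255 CPM. Both falls were among the 4 neighbours on the X chromosome. They were miR-424-5p by 1.0 ± 0.28 (0.0434) from 512 ± 133 to 256 ± 62.6 CPM and miR-450a-5p by 0.71 ± 0.20 (0.0434) from 272 ± 42.4 to 165 ± 10.6 CPM. The neighbour miR-503-5p, at -0.79 ± 0.25 and called without CM soft-gel replicates 2 or 3, did not pass. Nor did miR-542-5p, at 0.39 ± 0.35 and above the untreated mean in 2 of 3 libraries. With the background subtracted miR-542-5p stood at 1.07, so its size is not fixed.

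The remaining rises on the stiff gel were miR-1260b (1.30 ± 0.27, adjusted p = 0.0116), miR-603 (1.16 ± 0.27, 0.0207), miR-216a-5p (1.14 ± 0.23, 0.0116), miR-548n (0.92 ± 0.25, 0.0434) and miR-302f (0.79 ± 0.20, 0.0276), each higher in 3 of 3 libraries. For each of these only 1 of 3 untreated stiff-gel libraries exceeded the negative control threshold. With the background subtracted the rises were, in this order, 1.93, 1.93, 1.76, 1.42 and 1.29, so their sizes are not fixed. Also called was miR-3605-3p (adjusted p = 0.0132), above the negative control threshold in 3 of 3 CM and 0 of 3 untreated stiff-gel libraries. Its counts were 34, 52 and 91 against 18, 16 and 13. Its untreated level was at background, so the fitted change of 1.55 ± 0.33 does not fix the size of the rise, and it was 5.23 with the background subtracted. Mean counts were at most 54, the highest count of any plant or worm probe, for 5 of the 12, namely miR-302f, miR-3605-3p, miR-450a-5p, miR-548n and miR-603. Groups did not overlap for 70 of the 207 tested miRNAs, against 20.7 (10%) by chance, and 43 had an unadjusted p under 0.05, 30 higher and 13 lower. Of the list members, miR-205-5p, miR-216a-5p and miR-24-3p rose in their lists, and the miR-15/16 family held 1 member higher, miR-16-5p, and 1 lower, miR-424-5p. Adjusted over the list alone the miR-15/16 family held 1 higher and 2 lower and the miR-23/27/24 clusters 2 higher. The stromal vesicle cargo list then held 1 member higher and 1 lower.

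The count on the stiff gel was 1 without untreated stiff-gel replicate 1, 2 without untreated stiff-gel replicate 2, 6 without CM stiff-gel replicate 1 and 1 without CM stiff-gel replicate 3, and in each of the 12 such fits miR-483-3p was called. It was 9 without untreated soft-gel replicates 2 or 3, untreated stiff-gel replicate 3 or CM soft-gel replicates 1 or 3, and 10 of the 12 calls were kept without CM stiff-gel replicate 2. In each of the 12 fits all 12 miRNAs kept their sign and an unadjusted p under 0.05. Their CM and untreated libraries did not overlap, so kept signs here and below are no further support. Log2 changes ran from 1.04 to 1.48 for miR-1260b, from 1.11 to 1.45 for miR-205-5p and from -1.20 to -0.81 for miR-424-5p. The median standard error of the 12 was 0.29 without untreated stiff-gel replicate 1 or 2 and 0.27 without CM stiff-gel replicate 3, in place of 0.25. Without the 4 libraries rich in miR-4454 and miR-7975, among them 2 of the 3 untreated stiff-gel ones, 0 were called with edgeR and 28 had an unadjusted p under 0.05. That fit takes the spread of the lone untreated stiff-gel library from the other groups. In it 6 of the 12 had a larger and 6 a smaller fold change (miR-483-3p 1.76, miR-216a-5p 1.20, miR-205-5p 0.90, miR-424-5p -0.65). All 12 kept their sign, and their median standard error was 0.37 in place of 0.25. DESeq2 called 7, 6 higher and 1 lower. Scaling on total counts, with a median of 0.72 over all tested probes, gave 15 higher and 0 lower, scaling on the positive controls, with a median of 0.32, 22 higher and 0 lower, and scaling on housekeeping mRNAs 1 higher and 0 lower.

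On the soft gel, CM changed 0 of 207 miRNAs with edgeR, and 20 had an unadjusted p under 0.05, 12 higher and 8 lower. DESeq2 and limma-trend also called 0. The values nearest to passing were those of miR-365a-3p/miR-365b-3p, at 0.76 ± 0.17 (adjusted p = 0.0889, 1294 ± 183 against 764 ± 60.1 CPM, n = 3), and miR-503-5p, at -1.03 ± 0.25 (adjusted p = 0.0889, 374 ± 145 against 766 ± 104 CPM), each in 3 of 3 libraries. They were followed by miR-450a-5p (-0.72 ± 0.20, adjusted p = 0.173) and, at an adjusted p of 0.266, by miR-424-5p (-0.87 ± 0.28), miR-205-5p (0.79 ± 0.28), miR-193a-5p/miR-193b-5p (0.72 ± 0.24), miR-1286 (0.72 ± 0.25), miR-99a-5p (-0.59 ± 0.21), miR-146a-5p (0.54 ± 0.19), a regulator of NF-kB signalling, and miR-24-3p (0.52 ± 0.16). For miR-193a-5p/miR-193b-5p 1 of 3 untreated soft-gel libraries exceeded the negative control threshold, and for miR-1286 2 of 3. With the background subtracted these 2 were 1.56 and 1.17, and miR-450a-5p -1.08, so these sizes are not fixed. Groups did not overlap for 24 miRNAs, against 20.7 (10%) by chance. Adjusted over the list alone 3 members of the miR-15/16 family were lower and 0 higher, with a fry p of 0.0355 (adjusted p = 0.295) and p = 0.0421 with an estimated correlation. Likewise 1 member of the miR-23/27/24 clusters, miR-24-3p, was higher (fry adjusted p = 0.761). The count was 5, 2 higher and 3 lower, without untreated soft-gel replicate 1 and 1 without CM soft-gel replicate 3, and 2, miR-365a-3p/miR-365b-3p and miR-503-5p, both with a mean count of at least 100 required and with the miR-4454 level as a covariate.

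The CM effects on the soft and stiff gels, which share no library, had a Pearson correlation of 0.41 and a Spearman correlation of 0.39 across the 207 miRNAs, which are not independent replicates. In 100 simulations without any effect the central 95% of the Pearson correlations ran from -0.18 to 0.17. Those simulations drew probes independently, so these limits may be too narrow. With all 798 probes the observed Pearson correlation was 0.09. Of the 12 miRNAs called on the stiff gel 10 had the same sign on the soft gel, miR-483-3p and miR-1260b being the others, and 0 were called on both gels. An unadjusted p under 0.05 on both gels was found for 10 miRNAs, against 4.15 if the gels were independent, and 9 of them had the same sign, against 2.24.

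**Figure D3:**
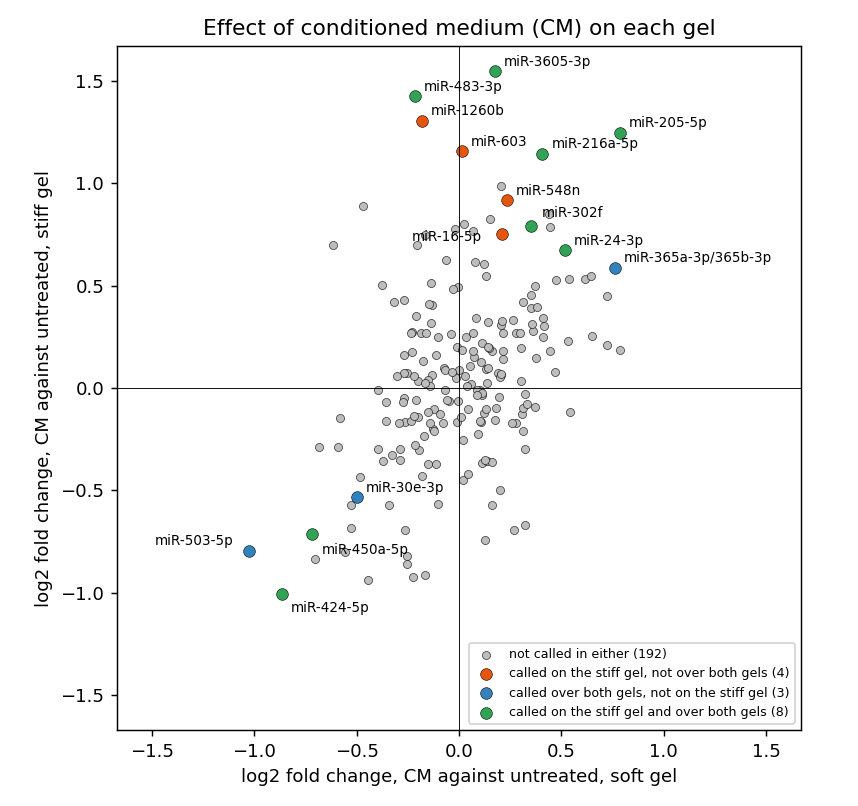
Log2 fold change of CM against untreated on the soft gel (horizontal) and on the stiff gel (vertical) for 207 miRNAs, coloured by where they were called. Of the called miRNAs 8 passed both on the stiff gel and over both gels, 4 on the stiff gel and not over both gels, and 3 over both gels and not on the stiff gel.

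The difference between the CM effects on the 2 gels, tested as an interaction, passed for 1 of the 207 miRNAs. It was 1.64 ± 0.34 for miR-483-3p (adjusted p = 0.0391), which with CM was higher in 3 of 3 stiff-gel libraries (1.42 ± 0.24) and below the untreated mean in 3 of 3 soft-gel ones (-0.22, adjusted p = 0.810, not passing). The next were miR-1260b, at 1.49 ± 0.38 (adjusted p = 0.127), miR-122-5p, at 1.31 ± 0.39 (0.255), miR-3605-3p, at 1.37 ± 0.46 (0.334), miR-603, at 1.14 ± 0.39 (0.334), and miR-222-3p, at -0.70 ± 0.24 (0.334), none of which passed. For miR-122-5p and miR-3605-3p 0 of 3 untreated stiff-gel libraries exceeded the negative control threshold. These sizes are thus not fixed. Of the 207 miRNAs 21 had an unadjusted p under 0.05. DESeq2 and limma-trend called 1 each, and 0 were called with a prior that was not robust, with total counts or housekeeping mRNAs as the scaling, with the background subtracted, without a filter or without the 4 libraries rich in miR-4454. The call stood without untreated stiff-gel replicate 2, CM stiff-gel replicate 1 or untreated soft-gel replicate 3, where miR-1260b made 2 calls, and 0 were called without any of the other 9 libraries, namely untreated soft-gel replicates 1 and 2, untreated stiff-gel replicates 1 and 3, CM soft-gel replicates 1, 2 and 3 and CM stiff-gel replicates 2 and 3. The log2 difference for miR-483-3p ranged from 1.47 to 1.87 over these 12 fits.

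Between the gels under CM, 1 miRNA differed with edgeR, miR-483-3p, higher on the stiff gel by 1.22 ± 0.24 (adjusted p = 0.0221, 841 ± 116 against 361 ± 35.3 CPM, n = 3, all 3 stiff-gel libraries above the soft-gel ones). At an adjusted p of 0.0644 the next were miR-320e (1.13 ± 0.29), miR-1252-5p (1.03 ± 0.26) and miR-1260b (1.03 ± 0.26), and miR-617 (0.96 ± 0.29), miR-210-5p (-0.86 ± 0.26), miR-603 (0.82 ± 0.26), miR-302f (0.68 ± 0.20), miR-181b-5p/miR-181d-5p (-0.68 ± 0.21) and miR-484 (0.52 ± 0.17) followed without passing. For miR-210-5p 0 of 3 stiff-gel libraries exceeded the negative control threshold. The size of its difference is thus not fixed, and was -2.46 with the background subtracted. The hypoxia-linked list, with 3 of 4 tested members lower, had a fry p of 0.00159 (adjusted p = 0.104), p = 0.0819 with an estimated correlation, and 1 member lower adjusted over the list alone. Groups did not overlap for 45 miRNAs, against 20.7 (10%) by chance, and 30 had an unadjusted p under 0.05. The count was 3 with DESeq2 and 0 without CM soft-gel replicates 1, 2 or 3 or CM stiff-gel replicates 2 or 3, where the log2 change of miR-483-3p ranged from 1.15 to 1.24. It was 5 without untreated soft-gel replicate 1, where miR-1252-5p, miR-1260b, miR-320e and miR-603 passed as well, 3 without untreated soft-gel replicate 2 (miR-1252-5p and miR-1260b) and 3 without CM stiff-gel replicate 1 (miR-320e and miR-617).

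Between the gels without treatment 0 of 207 miRNAs passed with edgeR, and 0 with DESeq2 or limma-trend. The smallest p was that of miR-122-5p, a miRNA of liver cells, at -0.82 ± 0.28 (adjusted p = 0.813, 75.9 ± 8.47 on the stiff against 138 ± 37.8 CPM on the soft gel, n = 3). At the same adjusted p stood miR-3161 (1.07 ± 0.51), miR-3605-3p (-0.75 ± 0.35), miR-607 (-0.69 ± 0.36), miR-302d-3p (-0.51 ± 0.22), miR-873-3p (-0.50 ± 0.22), miR-423-3p (-0.43 ± 0.20), and miR-29a-3p (0.46 ± 0.23), miR-146a-5p (0.45 ± 0.19) and miR-374b-5p (0.30 ± 0.15). The last 3 turned to -0.32, -0.33 and -0.44 when scaled on total counts, which moved the median of all tested probes to -0.75. Counts of miR-3161 were 47 to 89 in the 4 libraries rich in miR-4454 and 16 to 39 in the others. Its difference thus cannot be told apart from the level of the miR-4454 probe. For miR-122-5p, miR-3605-3p and miR-607 0 of 3 untreated stiff-gel libraries exceeded the negative control threshold. The sizes of these differences are thus not fixed, and with the background subtracted they were -6.97, -3.97 and -6.15. An unadjusted p under 0.05 was found for 6 miRNAs, and groups did not overlap for 20, against 20.7 (10%) by chance. The markers of absent tissues, which hold miR-122-5p and miR-302d-3p, had the smallest list p, 0.00422 with fry (adjusted p = 0.140), p = 0.0316 with an estimated correlation, and 1 member lower adjusted over the list alone. Over both media, 0 passed with edgeR, DESeq2 or limma-trend and 22 had an unadjusted p under 0.05. At an adjusted p of 0.218 stood miR-320e (0.69 ± 0.20), miR-1252-5p (0.68 ± 0.19), miR-210-5p (-0.61 ± 0.19), miR-302d-3p (-0.53 ± 0.16) and miR-302f (0.47 ± 0.14), and miR-29a-3p (0.42 ± 0.16, adjusted p = 0.417) turned to -0.08 when scaled on total counts. For miR-210-5p 0 of 3 libraries in each stiff-gel group exceeded the negative control threshold, so the size of its difference is not fixed.

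Whether CM moved miRNAs against the effect of stiffness was examined across the 207 miRNAs. The stiff-gel effect without treatment and the CM effect on the stiff gel had a Pearson correlation of -0.48, a Spearman correlation of -0.37 and a covariance of -0.0752. Both use the 3 untreated stiff-gel libraries with opposite sign. In simulations without any effect the central 95% ran from -0.64 to -0.35 for the correlation and from -0.0703 to -0.0306 for the covariance. The correlation thus lay within the limits that the shared libraries alone give, and the covariance slightly beyond them. Some simulations lie beyond such limits as well. Since the simulations drew probes independently, the limits may also be too narrow, and the excess of the covariance decides nothing. Of the miRNAs 0 were called in both with edgeR, and 3 had an unadjusted p under 0.05 in both, 0 of them with the same sign.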

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

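In this part the tests on the level of the miR-4454 and miR-7975 probe, on the negative control probes and without the 4 libraries rich in that probe were chosen only after the result was seen, while the splits of the libraries and the test on the plant probes were set before it.

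The effect of CM on hsa-miR-483-3p differed between the stiff and the soft gel by 1.64 on the log2 scale (SE 0.34, adjusted p = 0.0391 with edgeR), and this tested difference between the gels brought it here. When the 12 libraries were assigned to the 4 groups in 100 ways, the real one included, 8 gave at least the 1 call of the interaction, and the highest other count was 10. A chance assignment is therefore not excluded for that count. Between the gels under CM, where miR-483-3p was the 1 call, 1 of the 10 splits of the 6 libraries, the real one, gave a count as large, and the highest other count was 0. Splits of 6 libraries are too few to give a share under 0.05. The call of the interaction ended without any of 9 single libraries and stood in the 3 fits without untreated soft-gel replicate 3, untreated stiff-gel replicate 2 or CM stiff-gel replicate 1, and the log2 difference ranged from 1.47 to 1.63 in the 9 and from 1.47 to 1.87 over all 12.

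Control probes against rice miRNAs, which have no target in human RNA, gave counts above the negative control threshold, a signal in data that the comparisons do not use. The osa-miR414 probe exceeded it in 9 of 12 libraries, with 24 to 52 counts (median 36.0), and the osa-miR442 probe in 8, with 20 to 54 counts (median 45.5). The other 3 plant or worm probes exceeded it in 0 libraries.

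Of the 12 miRNAs called with CM on the stiff gel, 5 had mean counts in the range of those plant probes, and 4 of these were higher, the smallest rise being 0.79. Background that rose at all dim probes is argued against, since the mean of the negative control probes changed by -0.17 log2 (SE 0.22). The summed counts of the rice probes changed by -0.22 (SE 0.098), so the signal at those probes did not rise either. Off-target binding can differ from probe to probe, so this cannot decide on such binding at the called probes. With the level of the miR-4454 and miR-7975 probe as a covariate 12 of the 12 calls were kept and 14 were added, which argues against a trend with that level as the whole cause. Leaving out the 4 libraries rich in that probe left 1 untreated stiff-gel library, too few to decide. In that fit 6 of the 12 had a larger and 6 a smaller fold change, and their median standard error went from 0.25 to 0.37. All 12 kept their sign, but their groups did not overlap to begin with, so this is no support. Of the 10 splits of the 6 libraries, 1, the real one, gave 12 calls, the highest other count was 6, and the splits are too few for a share under 0.05, so an effect of CM stays open as a hypothesis.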

How the results depend on the processing

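Chosen after the result was seen were the tests with the miR-4454 level as a covariate, without the 4 libraries rich in miR-4454, and on probes above the highest plant or worm probe count. Counts of called miRNAs on the stiff gel with CM, 12 in the main setting, were 7 with DESeq2, 1 with housekeeping scaling, 22 with positive control scaling, 5 without a filter, 6 with a mean count of at least 100 (83 probes tested), 6 with limma on the authors' values, 22 with the 2 compared groups alone, 26 with the miR-4454 covariate, 0 without the 4 libraries and 7 above the plant and worm probes (124 probes tested). Over both gels, 11 in the main setting, they were 1 with total counts, 1 with housekeeping scaling, 19 with positive control scaling, 17 with background subtracted, 7 without a filter and 31 with the covariate. On the soft gel, in place of 0, they were 2 with a mean count of at least 100 and 2 with the covariate. Between the gels under CM, in place of 1, they were 3 with DESeq2, 0 with total counts, 0 with housekeeping scaling, 12 with positive control scaling, 5 without a filter, 7 with the covariate and 0 without the 4 libraries. For the interaction, in place of 1, they were 0 with total counts, 0 with housekeeping scaling, 2 with positive control scaling, 0 with background subtracted, 0 without a filter, 0 with a prior that was not robust, 2 with the covariate and 0 without the 4 libraries. Total counts include the miR-4454 and miR-7975 probe, at 11.1% to 72.8% of endogenous counts per library. Scaling on them thus shifts all other probes with the level of that probe. Fewer probes or libraries were tested where stated, and for the other settings the cause was not tested. Between the gels without treatment and over both media the count was 0 in every setting run.

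Leaving out each library in turn gave 1 to 17 calls on the stiff gel with CM (1 without untreated replicate 1 or CM replicate 3, 2 without untreated replicate 2, 6 without CM replicate 1), 0 to 5 on the soft gel (5 without untreated soft-gel replicate 1, 1 without CM soft-gel replicate 3), 0 to 5 between the gels under CM, 0 to 2 for the interaction, 7 to 38 over both gels (38 without untreated soft-gel replicate 1, 7 without untreated soft-gel replicate 3), and 0 to 0 for both gel comparisons without a call. With the replicate number as a block, 10 were called on the stiff gel, 13 over both gels, 1 between the gels under CM, 1 for the interaction, and 0 on the soft gel and in both other gel comparisons. All 12 calls on the stiff gel and all 11 over both gels kept their direction in each setting that tested them.

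Across miRNAs, the correlation between the stiffness effect and the CM effect on the stiff gel, -0.48 in the main setting, was -0.57 without a filter and -0.36 with a mean count of at least 100, and that between the CM effects on both gels, 0.41 in the main setting, was 0.088 without a filter. With total counts as the scaling, log2 values changed sign between the untreated gels for miR-146a-5p (-0.33), miR-29a-3p (-0.32) and miR-374b-5p (-0.44), over both media for miR-29a-3p (-0.076), and with CM over both gels for miR-10a-5p (0.023), miR-10b-5p (0.036), miR-194-5p (0.10), miR-140-5p (0.21), miR-199b-5p (0.27) and miR-301a-3p (0.24). Positive control scaling also turned miR-199b-5p (0.048), and leaving out the 4 libraries turned miR-107 (-0.060). None of these had been called, and total counts moved the median of all tested probes to 0.47 over both gels, -0.75 between untreated gels, 0.15 with CM on the soft gel, -0.17 between gels under CM, 0.55 for the interaction and -0.46 over both media. Positive control scaling moved it to 0.28 between gels under CM, 0.25 for the interaction and 0.12 over both media, and housekeeping scaling to 0.14 between untreated gels and 0.11 over both media. With camera in place of fry the direction turned, with p values of 0.886 (inflammation-linked) and 0.985 (DLK1-DIO3) between untreated gels, 0.952 (let-7), 0.875 (miR-17-92), 0.832 (inflammation-linked) and 0.848 (p53-linked) with CM on the stiff gel, 0.988 (p53-linked) on the soft gel, 0.992 (let-7), 0.948 (miR-200) and 0.927 (absent tissues) between gels under CM, 0.872 (miR-17-92) for the interaction, and 0.904 (fibrosis-opposing), 0.916 (miR-17-92) and 0.892 (p53-linked) with CM over both gels. The cause was not tested, and none of these lists had passed.

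The negative control threshold of each library limits which dim probes are seen: 118 and 130 endogenous probes exceeded it in the untreated stiff-gel replicates 2 and 1, with thresholds of 60.8 and 48.3 counts and totals of 414239 and 421456, and 211 in untreated soft-gel replicate 2, with a threshold of 23.3 and a total of 176711. Of the tested probes, 107 of the 207 exceeded it in all 12 libraries, and 83 had a mean count of at least 100. Median standard errors over both gels were 0.17 with TMM, 0.36 with total counts and 0.27 with housekeeping scaling, so the last 2 resolve smaller changes less well.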

Other observations

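In this part the tests on the level of the miR-4454 and miR-7975 probe, without the 4 libraries rich in it, on how many calls the fits without single libraries had to keep, and on neighbouring miRNA genes were chosen only after the result was seen, while the splits of the libraries and the fits without single libraries were set before it.

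Several miRNAs usually named as markers of the cell types at hand stayed near background. Of the kidney tubule list, miR-192-5p had a mean of 13.3 counts, miR-204-5p 9.58 and miR-211-5p 11.2, above the negative control threshold in 0 of 12 libraries, and miR-215-5p 21.6, above it in 2. Of the stromal markers, miR-145-5p had 12.2 counts, miR-214-3p 12.5 and the shared probe of miR-199a-3p and miR-199b-3p 14.9, above it in 0 libraries, and miR-143-3p had 23.5 counts with CM and 16.7 without, also above it in 0. Of the blood and endothelial list miR-126-3p was tested, at 46.7 counts and a log2 change with CM over both gels of -0.05 ± 0.13 (adjusted p = 0.862 with edgeR), and miR-451a, a red cell miRNA, had 12.3 counts. Of the 14 probes matched to the list of the placental C19MC cluster 0 met the filter for testing. The highest mean among them, that of miR-519d-3p, was 24.8 counts. The list does not hold every miRNA of the cluster: miR-525-3p, the other arm of the listed miR-525-5p, is an example that met the filter. The list thus cannot decide whether the cluster as a whole stayed near background.

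With CM over both gels 11 miRNAs were called, and 4 of 100 splits within each gel, the real one included, gave as many. That share is under 0.05, but the splits were a sample of those possible, and each of the 7 comparisons was split. Chance is thus not excluded. The highest other split gave 26 calls and exchanges untreated soft-gel replicate 1 and CM soft-gel replicate 3. A trend with the level of the miR-4454 and miR-7975 probe is argued against as the whole cause, since 11 of the 11 calls were kept with that level as a covariate and 20 were added; without the 4 libraries rich in it 13 were called, 4 of them among the 11, while all 11 kept their sign, 6 with a larger fold change, 10 had an unadjusted p under 0.05, and their median standard error was 0.20 in place of 0.16. A single library is argued against as well, since at least 7 of the 11 calls were kept in each of the 12 fits that left one out. An effect of CM may thus underlie these calls, as a hypothesis found and tested on the same libraries, and a change of medium without stem cell products cannot be told apart from it by this design.

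Of the 4 miRNAs called lower with CM over both gels, 3 are among the 4 tested miRNAs of the neighbouring genes MIR424, MIR503, MIR542 and MIR450A, a set noticed from these calls. A candidate explanation is lower transcription of the whole cluster, and it stays open, because the remaining tested member, miR-542-5p, had a log2 change of 0.37 with a 95% interval from -0.14 to 0.88 (adjusted p = 0.443) at a mean of 30.2 counts. A single library is argued against as the cause, since the 3 calls stood in 12 of the 12 fits that left one out.

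For the comparisons without calls or with counts at an unadjusted p under 0.05, the splits gave the following. Between untreated gels the real count was 6, 5 of 10 splits gave as many, and the highest other was 56, with 27 calls, in the split that sets the 3 libraries rich in miR-4454 and miR-7975 against the other 3. With CM on the soft gel the real count was 20, 4 of 10 splits gave as many, and the highest other was 41. Both designs have too few splits for a share under 0.05. For the gels over both media the real count was 22, 12 of 100 splits gave as many, the highest other was 63, and chance is not excluded. That highest split also sets those 3 untreated libraries together, so both high counts go with a structure of the untreated libraries.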
